A study of Mus musculus with 4 samples.

How the data were processed

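C2C12 cells, an established mouse myoblast line that forms multinucleated myotubes when serum is lowered, were differentiated for 3 days with or without interferon-gamma (IFN-γ) at 1 ng/ml. Total RNA was hybridised to 4 Agilent mouse arrays of 2 colours, and per the labels every array held RNA of treated cells in Cy5 and of untreated control cells in Cy3, from 8 µg of RNA. No array had the dyes the other way round, so a dye bias of a probe or transcript lies in the same direction as the treatment on all 4 arrays and could not be estimated. The labels call the treated samples biological replicates 1 to 4 but do not say whether the controls were 4 separate cultures, so p-values measure the spread between these arrays, part of which may be technical. The labels also disagree on the horse serum of the differentiation medium, given as 2% in the treatment protocol and 10% in the sample source. All 4 arrays lay on 1 slide and had 1 scan, which left no slide or scan batch to test. The file header names a genome build that differs from the assembly of the gene table used for symbols, so coordinates are not printed.

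The spot intensities in the deposited scanner files were made by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers. Those files hold median spot intensities and median local backgrounds for each channel, background-subtracted and dye-normalised processed intensities, and the log10 ratio of Cy5 to Cy3, per the file headers. Per the labels and the design text, the authors then took the values into GeneSpring GX, log2 transformed them, filtered on detection flags, and applied an unpaired test with Benjamini-Hochberg adjustment and a fold change of 2. The authors' value table is in log2 units; set against the scanner log10 ratios it had slopes of 3.32 on all 4 arrays, with 3.32 expected for a change from log10 to log2, and correlations of 0.999 to 1.00 across probes. Its direction is therefore Cy5 over Cy3, its column medians lay between −0.125 and −0.105, and how it was centred stays unknown.

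Median spot intensities were corrected for local background with normexp and an offset of 50, then log2 ratios of treated over control were normalised within each array by loess in limma 3.58.1 under R 4.3.3. The plan, fixed before the data were examined, assumed mean spot intensities and a gene name column, but the files hold medians and sequence accessions only, so medians were used. Control spots had weight 0 in the loess, outlier-flagged spots were left out and spots of 1 probe were averaged. Of 43020 spots per array that were not controls, which held 39429 probes, 26055 probes received 1 gene symbol through their accession in the RefSeq gene table, 0 received several and 13374 received none. The named probes covered 19751 genes. A probe was tested when it was well above background in the same channel on at least 3 of the 4 arrays, and each gene was represented by its brightest tested probe. This gave 15673 genes, of which 3921 had 2 or more tested probes. The mean log2 ratio of each gene was tested against 0 with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over genes at 0.05, with no covariates. Adjusted p-values in the text come from this limma fit unless another test is named.

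Genes not well above background in the control channel on any array have a bound on their fold only, and their fitted log2 ratios depend on the background level. The bound was computed from means of normalised channel values after loess and Aquantile normalisation, with the control set at the higher of its own signal and the lowest signal among probes well above background on each array. Such bounds are open to dye bias. Of the tested genes, 1284 were in this state in the control channel and 0 in the treated channel. Control RNA was always in Cy3, the channel with lower medians and fewer probes above background. A probe could be tested through either channel, so this split cannot be read as a count of genes silent in control cells.

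The 30 lists of genes, made of 24 pathways or gene groups and 6 sets of markers for cell types, were written before the data were examined. Shifts of lists were tested with camera of limma at its preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Named genes follow a rule of 3 parts fixed at the same time. The first part takes the 10 largest rises and 10 largest falls past the threshold with 1 sign on all arrays, leaving out clone names and other bare identifiers. The second takes up to 4 called members of each list with the largest change and the brightest member that did not pass, or the 2 brightest where none passed. The third is a fixed set of interferon, myogenic and insulin-like growth factor genes. Myostatin, in that set, was not well above background and was not tested.

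Median intensities were 97, 81, 79.8 and 92 in Cy3 and 224, 149.5, 264 and 234 in Cy5 for replicates 1 to 4. Between 22453 and 25905 probes were well above background in the control channel and between 28548 and 30148 in the treated channel. Outlier spots numbered 197 to 291 per array, and 0 spots were saturated. Log2 ratios of replicate 2 correlated less with the other arrays (r = 0.63 to 0.72 across genes, which are not independent) than those arrays did among themselves (r = 0.86 to 0.90). The number of arrays limits the precision. The procedure was tested on simulated log2 ratios of 15610 genes with the spread of the real genes, with known changes added to a seeded set of genes. It recovered 41.8% of changes of 0.5 on the log2 scale, 82.1% of changes of 1 and 98.5% of changes of 2, and 1.99% of its calls were false. These sizes were given to 67, 67 and 66 genes. Noise was drawn independently for each gene, with no dye bias and no effect shared by an array, so these shares need not hold for the real data.

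Alternatives varied the background correction, the normalisation, the filter on dim probes, outlier spots, the choice of probe, the test, the threshold and the replicates. A change of the spot summary and the omission of saturated probes were intended but not run, because the files hold medians only and no spot was saturated. Other alternatives were chosen after seeing the data and are named as such. Probes with no symbol were tested only in the alternative that tests each probe.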

Results

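Gene expression was measured in C2C12 mouse myoblasts on day 3 of myogenic differentiation, with IFN-γ at 1 ng/ml against no cytokine. Each of 4 arrays set 1 treated culture against an untreated control, and the log2 ratio of treated over control is the unit below, with its SD over the arrays. Median intensities per array lay between 79.8 and 97 for control RNA, always in Cy3, and between 149.5 and 264 for treated RNA, always in Cy5. Dye and treatment cannot be told apart in this difference. The study asked how IFN-γ changes the transcription of genes that control the formation of skeletal muscle cells. Myostatin, a negative regulator of muscle growth, was not well above background.

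IFN-γ raised a large interferon programme and antigen presentation, raised most cell cycle genes by smaller amounts, and lowered genes of the contractile apparatus relative to the bulk of genes, the last with a positive median under median centring. Expression of 3111 of 15673 genes was higher and of 2173 lower at an adjusted p under 0.05 (limma), and 281 were higher and 154 lower by at least 2-fold. The counts at least 2-fold higher and lower were 779 and 368 with Feature Extraction's ratios, 4422 and 25 under median centring, and 479 and 2421 with centring on the tested genes. The largest rise was that of Gbp3, a guanylate-binding GTPase of cell-autonomous defence, at 7.08 ± 0.32 (SD, n = 4), a 135-fold change with an adjusted p of 2.55e-06 and the same sign on 4 of 4 arrays. Igtp rose by 6.65 ± 0.23, Gbp4 by 5.78 to 6.38 on the 4 arrays, Tgtp2 by 5.43 ± 0.18, Ifi47 by 5.24 ± 0.24 and Gbp7 by 5.04 ± 0.16. Psmb8, a catalytic subunit of the immunoproteasome, rose by 4.86 ± 0.20, and Irgm2, Gvin1 and Rtp4 rose by 4.78, 4.69 and 4.68. The second probes of Tgtp2 and Gvin1 had 3.23 and 2.53. Most called changes were small, since 4849 of the 5284 called genes, or 91.8%, lay under 2-fold, and the median absolute log2 ratio of called genes was 0.45. Without replicate 1 the counts were 2074 higher and 1299 lower, without replicate 3 they were 1600 and 927, without replicate 4 they were 1815 and 1083, and without replicate 2, the array that correlated least with the others, they were 4062 and 2971. All 4 arrays had 1 dye orientation, so small changes could not be separated from dye bias, and of called genes 58.9% were higher under loess but 79.8% under median centring, which put the median of tested genes at 0.69, while centring on the tested genes, chosen after seeing the data, gave 4707 higher and 5480 lower.

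**Figure D1:**
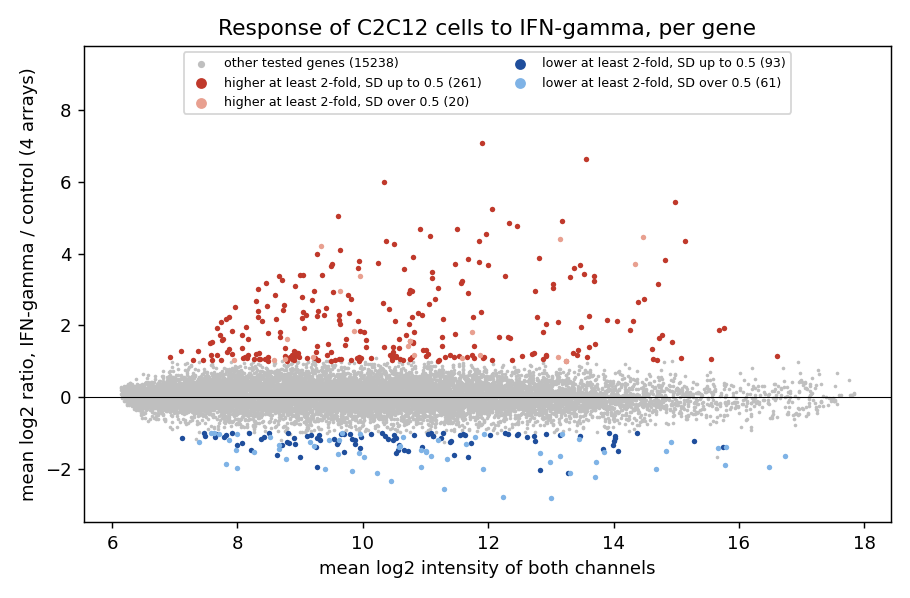
Mean log2 ratio of IFN-γ over control against mean log2 intensity for each tested gene, with 1 point per gene and genes changed at least 2-fold at an adjusted p under 0.05 in colour by their SD over 4 arrays. Of the 154 genes that were at least 2-fold lower, 61 had an SD over 0.5, against 20 of the 281 that were at least 2-fold higher.

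Some members of the signalling list rose, whereas the receptor genes did not pass the test. Irf1, an interferon regulatory factor, rose by 2.74 ± 0.20 and Batf2 by 4.35 ± 0.29. Socs1, an inhibitor of JAK kinases, rose by 1.75 ± 0.25. The receptor genes Ifngr1 and Ifngr2 had ratios of 0.25 ± 0.20 and 0.02 ± 0.28, the kinase gene Jak2 had 0.26 ± 0.23 and Socs3 had −0.13 ± 0.21. In the list of JAK-STAT signalling and interferon regulatory factors, 11 of 28 tested members rose, 2 fell and 15 did not pass, and adjusted over the list alone 12 rose and 2 fell. Its median was 0.25 and its shift had an adjusted p of 0.00329 (camera), and adjusted p = 0.242 with an estimated correlation. The second tested probe of Irf1 had a ratio of 0.29. The list median was 0.098 with both channels above background on all arrays, and 1.06 and 0.38 under the 2 kinds of median centring.

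Genes of interferon-induced defence rose nearly as complete groups. Of 17 interferon-inducible GTPases, which act against intracellular pathogens, 16 rose and 1 did not pass, with a median of 3.68 (camera adjusted p = 1.31e-17, and adjusted p = 0.242 with an estimated correlation). The member that did not pass was Gbp6, whose brightest probe had 0.00 ± 0.57 while its second probe had 4.67. Of 34 genes of the type I interferon antiviral list, 31 rose and 3 did not pass (32 rose adjusted over the list alone), with a median of 2.41 (camera adjusted p = 3.05e-24, and adjusted p = 0.242 with an estimated correlation). Examples were Bst2, which tethers budding virions, at 4.36 ± 0.17, Oasl2 at 4.27 ± 0.08 and Oas1a, an oligoadenylate synthetase, at 4.00 ± 0.39, with 2.31 on its second probe. Ifitm3 had 0.20 ± 0.73 and did not pass.

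Antigen presentation genes of both classes rose. Of 25 genes of MHC class I processing and presentation, 22 rose and 3 did not pass, with a median of 2.91 (camera adjusted p = 1.99e-18, and adjusted p = 0.242 with an estimated correlation). Psmb9, another immunoproteasome subunit, rose by 4.55 ± 0.22, Nlrc5, the transactivator of class I genes, by 4.50 ± 0.19 and H2-Q7 by 4.42 ± 0.59. H2-Q4 had −0.07 ± 0.76. Of 14 genes of MHC class II presentation, 10 rose and 4 did not pass, with a median of 0.88 (camera adjusted p = 8.43e-06, and adjusted p = 0.242 with an estimated correlation). Cd74, the invariant chain, rose by 3.73 ± 0.31, H2-DMb1 by 3.60 ± 0.19, H2-Eb1 by 2.29 ± 0.12 and Ciita, the class II transactivator, by 1.04 ± 0.60. The second probe of Nlrc5 had a ratio of 0.71. Under median centring the class II list no longer passed (adjusted p = 0.139, the highest of its settings with the preset correlation, which went down to 1.85e-10), and with Feature Extraction's ratios its median was 1.84.

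Secreted immune mediators rose in part. Of 27 chemokine and cytokine genes, 19 rose, 3 fell and 5 did not pass (20 and 3 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 1.25e-06, and adjusted p = 0.242 with an estimated correlation). Cxcl10 and Cxcl9, which attract T cells, rose by 4.21 ± 0.56 and 3.81 ± 0.27, Cxcl5 by 3.39 ± 0.61 and Ccl8 by 2.97 ± 0.60, whereas Il6 had −0.12 ± 0.12. The second probe of Cxcl9 had 2.99. Of 18 complement genes, 8 rose and 10 did not pass, with a median of 0.17 (camera adjusted p = 0.00174, and adjusted p = 0.292 with an estimated correlation). C1s1 and C1ra, proteases of the classical pathway, rose by 3.70 ± 0.39 and 3.17 ± 0.27, Cfb by 3.56 ± 0.22 and Serping1, their inhibitor, by 2.29 ± 0.41. Cd55 had 0.15 ± 0.45. Under median centring neither list passed (adjusted p = 0.132 and 0.818, the highest of their settings with the preset correlation, which went down to 6.91e-17 and 1.68e-07), and with centring on the tested genes the complement list did not pass either (0.150). With Feature Extraction's ratios the medians were 1.63 and 0.72, and the complement median was 1.29 with both channels above background on all arrays, 0.76 with each probe on its own and 0.29 without replicate 2.

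**Figure D2:**
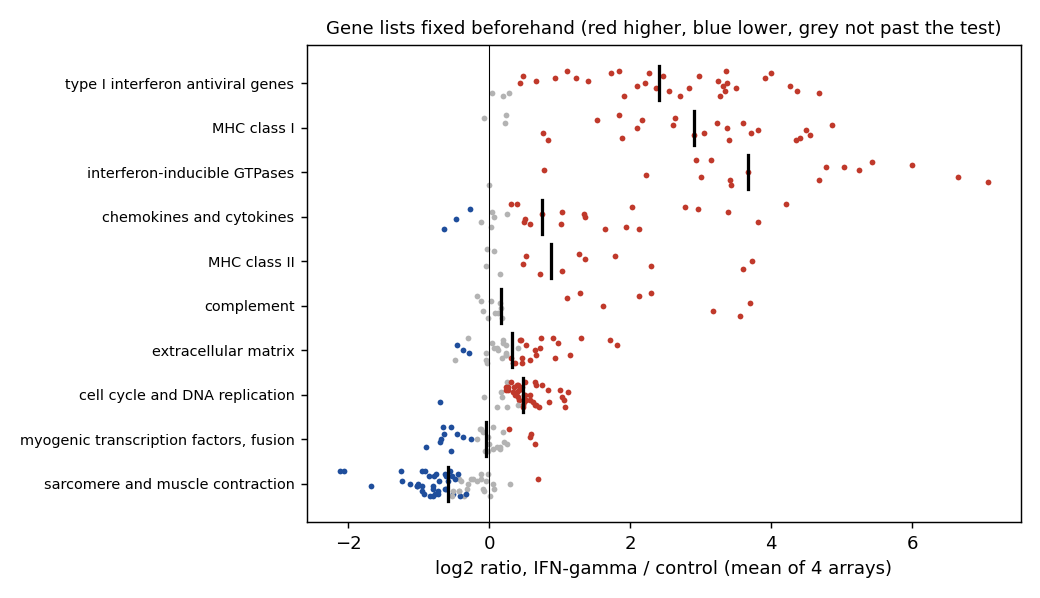
Log2 ratio of IFN-γ over control for the tested members of 10 lists, with 1 point per gene (mean of 4 arrays) and a vertical bar at the list median. The medians run from 3.68 for the interferon-inducible GTPases to −0.59 for the sarcomere list, which had 0.31 under median centring.

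Genes of the contractile apparatus fell as a group, although their median turned positive under median centring, whereas the myogenic regulators Myod1 and Myog did not pass the test under loess. Of 61 sarcomere and contraction genes, 38 fell, 1 rose and 22 did not pass, and adjusted over the list alone 43 fell and 1 rose. The list median was −0.59 (camera adjusted p = 1.33e-14, and adjusted p = 0.242 with an estimated correlation). Myh4, a fast myosin heavy chain, fell by 2.12 on the log2 scale with an SD of 0.36 (adjusted p = 0.00031), Mylpf, a fast regulatory light chain, had −1.67 ± 0.36 and Chrng, the embryonic subunit of the acetylcholine receptor, had −1.25 ± 0.28. Neb, which encodes nebulin, had −2.06 ± 0.45, but its second probe had −0.09. The embryonic myosin gene Myh3 had −0.62 ± 0.06 on its first probe and −0.57 on its second. Skeletal actin, Acta1, had −0.36 ± 0.57 and did not pass, with −1.18 on replicate 2. The list median was −0.85 on replicate 2 and −0.45, −0.72 and −0.37 on replicates 1, 3 and 4. Under median centring it was 0.31 against 0.69 for all tested genes and the shift did not pass (adjusted p = 0.115, the highest of its settings with the preset correlation, which went down to 3.22e-16), while centring on the tested genes, chosen after seeing the data, gave −0.36 with an adjusted p of 0.00252.

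Myod1 and Myog, the transcription factors that commit and differentiate myoblasts, had ratios of −0.02 ± 0.08 and −0.01 ± 0.40, and Mef2c had 0.11 ± 0.28. Myf5, a regulator of early myoblasts, rose by 0.60 ± 0.15. Of 30 myogenic transcription factor and fusion genes, 4 rose, 10 fell and 16 did not pass, with a median of −0.04 (camera adjusted p = 0.181). That list passed downward with the mean of a gene's probes (adjusted p = 0.0315) and with each probe on its own (0.0166), and its settings with the preset correlation went up to 0.898. Mymk, required for myoblast fusion, had −0.90 ± 0.42, Cav3 −0.70 ± 0.46, Cdh2, which encodes N-cadherin, −0.68 ± 0.18 and Hes1 −0.66 ± 0.40, all past the threshold, and Itga7 had −0.08 ± 0.06. Under median centring the signs of Mymk, Cav3, Cdh2, Hes1 and Myh3 turned positive, below the median of tested genes, and Myod1, Myog and Itga7 passed with 0.97, 1.02 and 0.96, above that median of 0.69. This setting subtracts a constant from each array and leaves any dependence of the ratio on intensity in place. Rplp0 and Hspb1, unchanged under loess, also lay above that median, so such passes were not particular to myogenic genes. With centring on the tested genes Myod1 and Itga7 passed with 0.29 each, and Myog had 0.35 and did not pass.

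**Figure D3:**
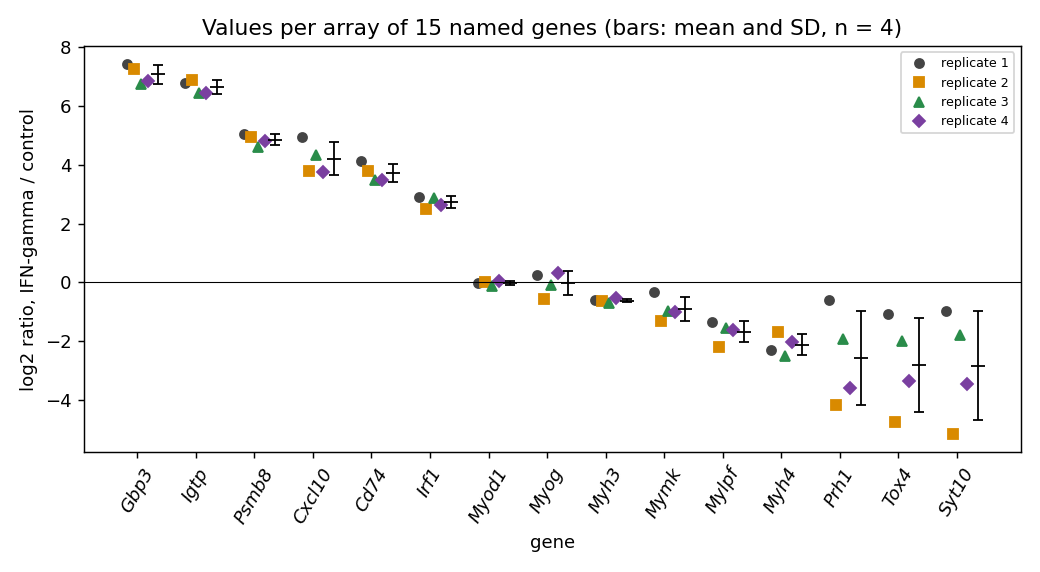
Log2 ratio of IFN-γ over control on each of 4 arrays for 15 named genes, with the mean and SD beside the points. Gbp3 lay at 7.08 ± 0.32, Myod1 at −0.02 ± 0.08 and Syt10 at −2.83 ± 1.86, the last with −5.15 on replicate 2 and −0.96 on replicate 1.

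The remaining genes with the largest mean falls varied widely between arrays. Syt10 had −2.83 ± 1.86, Tox4 −2.80 ± 1.60, Prh1 −2.57 ± 1.61, Tuba3b −2.35 ± 1.68, Nanos3 −2.23 ± 1.59, Foxl2 −2.13 ± 1.43, Ndufaf5 −2.12 ± 1.75 and Inpp5e −2.08 ± 1.11. Each of these 8 genes was lowest on replicate 2 and closest to 0 on replicate 1. The second probe had 0.58 for Tox4, 0.06 for Inpp5e, −0.21 for Foxl2 and −0.68 for Prh1. When each probe was tested, the second of Prh1 and the third of Inpp5e were also called lower, whereas the second probes of Tox4, Inpp5e and Foxl2 were not.

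Cell cycle genes rose by small amounts as a group. Of 46 cell cycle and DNA replication genes, 38 rose, 1 fell and 7 did not pass (41 and 1 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 5.40e-11, and adjusted p = 0.242 with an estimated correlation). Mcm4, a subunit of the replicative helicase, rose by 1.11 ± 0.28, and the mitotic kinesins Kif20a and Kif11 by 1.08 ± 0.34 and 1.04 ± 0.36. Tpx2, a spindle assembly factor, rose by 1.06 ± 0.34 on its first probe, with 0.15 on its second. Rrm2 had 0.19 ± 0.12. The median of the cell cycle and DNA replication list was 1.39 under median centring, against 0.69 for all tested genes. Of 19 genes of cyclin-dependent kinase inhibition and cell cycle exit, 7 rose, 3 fell and 9 did not pass (8 and 3 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.600, but 0.0353 and 0.0162, upward, under the 2 kinds of median centring). Among its members that rose were genes that promote the cell cycle. Myc rose by 1.11 ± 0.48, Ccnd1, which encodes cyclin D1, by 0.88 ± 0.21 and Cdk6 by 0.85 ± 0.19. Cdkn1a, which encodes the inhibitor p21 that rises as myoblasts leave the cell cycle, had −0.99 ± 0.82 with an adjusted p of 0.0435. It was lower on 3 of 4 arrays, with 0.20 on replicate 1, and its second probe had −0.21; under median centring it had 0.019.

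Growth factor genes moved in both directions. Igf1, a growth factor that promotes myogenesis, had −0.57 ± 0.11 (adjusted p = 0.00263), with −0.54 on its second probe. Of its 4 tested probes 1 was not called lower. Igf2 had −0.35 ± 0.18. Igfbp2 had −0.59 ± 0.17 and Irs2 −0.52 ± 0.38, both past the threshold, and Igfbp3, a binding protein, rose by 1.06 ± 0.37. Igf1r had 0.04 ± 0.33 and Igfbp5 had −0.07 ± 0.28. Of 22 genes of the insulin-like growth factor axis, 2 rose, 7 fell and 13 did not pass (camera adjusted p = 0.158). Of 27 genes of the transforming growth factor beta and myostatin axis, 9 rose, 3 fell and 15 did not pass (10 and 3 adjusted over the list alone; camera adjusted p = 0.816, but 0.0471, upward, with centring on the tested genes). Tgfb2 had −1.47 ± 0.10 (adjusted p = 6.4e-05), with −1.77 on its second probe. Fst, which encodes the myostatin antagonist follistatin, had −1.35 ± 0.26 and Grem1 had −0.85 ± 0.56, both past the threshold, and Ccn2 rose by 0.99 ± 0.08. Fstl1 had 0.38 ± 0.68. Under median centring the signs of Igf1, Igfbp2, Irs2 and Grem1 turned positive, below the median of tested genes.

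Extracellular matrix genes rose more often than they fell, as did fibroblast markers, of which 5 of 8 rose and 1 fell. Of 40 such genes, 20 rose, 3 fell and 17 did not pass (21 and 5 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.000832, and adjusted p = 0.242 with an estimated correlation). Fbln1 rose by 1.81 ± 0.76, Spp1, which encodes osteopontin, by 1.72 ± 0.27, Fbn1, which encodes fibrillin, by 1.30 ± 0.20 and Col3a1 by 1.15 ± 0.30, while Fn1 had 0.24 ± 0.50. The matrix list had a median of 1.33 under median centring, against 0.69 for all tested genes. Of 27 integrin and adhesion genes, 8 rose, 4 fell and 15 did not pass (11 and 5 adjusted over the list alone, camera adjusted p = 0.598). Vcam1 rose by 1.42 ± 0.19 over 3 arrays and Itga6 had −0.99 ± 0.16, past the threshold. Cdh11 rose by 0.84 ± 0.20 with −0.02 on its second probe. Of 28 matrix metalloproteinase and inhibitor genes, 9 rose, 4 fell and 15 did not pass (13 and 4 adjusted over the list alone, camera adjusted p = 0.108). The plasminogen activators Plau and Plat rose by 1.11 ± 0.53 and 0.98 ± 0.10, and Adamts1 had −0.96 ± 0.13, past the threshold. Under median centring Itga6 and Adamts1 had 0.026 and 0.040.

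Among cell death genes, 14 of 33 rose, 3 fell and 16 did not pass (16 and 4 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0130, and adjusted p = 0.242 with an estimated correlation). Casp1, the inflammatory caspase, rose by 2.11 ± 0.34, Bid by 1.08 ± 0.10 and Casp8 by 1.04 ± 0.23. The cell death list had a median of 1.12 under median centring, against 0.69 for all tested genes. Of 30 NF-kappaB and pattern recognition genes, 10 rose, 6 fell and 14 did not pass, with a median of −0.04 and a mean of 0.12 (camera adjusted p = 0.906), and Nod1, an intracellular sensor, rose by 1.66 ± 0.18. Of 20 endoplasmic reticulum and heat stress genes, 10 rose, 5 fell and 5 did not pass (camera adjusted p = 0.153, but 0.0130 and 0.00207, upward, under the 2 kinds of median centring), with Hsp90b1 higher by 1.05 ± 0.17 and Asns, an amino acid response gene, lower on 4 of 4 arrays, with −1.20 to −0.76 under loess and a mean of 0.015 under median centring. Of 21 muscle proteolysis and autophagy genes, 4 rose, 4 fell and 13 did not pass, with a median of 0.12 and a downward sign in camera (adjusted p = 0.906).

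Metabolic lists moved little as groups. Of 30 respiratory chain genes, 3 rose, 8 fell and 19 did not pass (3 and 9 adjusted over the list alone), with a median of −0.12 (camera adjusted p = 0.0402, and adjusted p = 0.553 with an estimated correlation). The direction of this list turned under both kinds of median centring, to 0.89 and 0.22, and with median centring over all probes it passed upward (camera adjusted p = 0.0353). It did not pass without replicate 2 (adjusted p = 0.107), with Feature Extraction's ratios (0.0558) or with separate channels (0.135), among others, in a range of 0.0112 to 0.229 over its settings with the preset correlation. Its members with the largest falls, Cox8b at −1.19 ± 0.87 and Cox6a2 at −1.05 ± 0.71, are subunit forms of striated muscle, and both are among the 61 falls with an SD over 0.5, with −2.44 and −2.02 on replicate 2. Of 35 glucose and lipid genes, 12 rose, 7 fell and 16 did not pass (camera adjusted p = 0.651), and Lpl, which encodes lipoprotein lipase, rose by 1.25 ± 0.13 on its first probe, with 0.80 on its second. Of 21 nitric oxide, redox and tryptophan genes, 7 rose, 2 fell and 12 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.158), and Wars, the tryptophanyl-tRNA synthetase, rose by 1.87 ± 0.33 on its first probe, with 1.09 on its second. Of 15 house-keeping genes, 4 rose, 0 fell and 11 did not pass (camera adjusted p = 0.159, but 0.0304 and 0.00352, upward, under the 2 kinds of median centring), with Actb at 0.75 ± 0.37, and with Rplp0 at −0.0014 ± 0.12 under loess but at 1.05 and 0.38 under median centring over all probes and over tested genes.

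Markers of other cell types gave no uniform picture. Of 14 macrophage and leukocyte markers, 2 rose, 2 fell and 10 did not pass, with a median of 0.051 and a downward sign in camera (adjusted p = 0.952, but 0.0353 and 0.0184 under the 2 kinds of median centring), and of 6 endothelial markers 1 fell and 5 did not pass (camera adjusted p = 0.432). Of 4 adipocyte markers 2 rose and 2 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.147), and of 7 osteoblast markers 3 rose and 4 did not pass (camera adjusted p = 0.0858). Of 8 fibroblast markers, 5 rose, 1 fell and 2 did not pass, with a median of 0.45 (camera adjusted p = 0.0357, and adjusted p = 0.242 with an estimated correlation), and Ly6a, which is also interferon-inducible, rose by 2.12 ± 0.43. Of 8 smooth muscle markers, 5 fell and 3 did not pass, with a median of −0.56 (camera adjusted p = 0.00493, and adjusted p = 0.242 with an estimated correlation). Among them Des, which skeletal muscle also expresses, had −1.23 ± 0.26 and Cnn1 −1.09 ± 0.41, while Acta2 had 0.00 ± 0.40. Under median centring the fibroblast and smooth muscle lists did not pass (adjusted p = 0.784 and 0.137, the highest of their settings with the preset correlation, which went down to 0.00342 and 0.00133), and the fibroblast list also did not pass with centring on the tested genes (0.285), both channels above background (0.0662), the methods' t-test (0.0516) or disagreeing probes left out (0.0503), and the smooth muscle list with centring on the tested genes (0.0527). The fibroblast median was 0.21 with no filter on dim probes and 0.73 with Feature Extraction's ratios. For all lists whose count adjusted over the list alone is not given, it equalled the count over all genes.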

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

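The tests on the falls that vary between arrays, on replicate 2 and on second probes were chosen after the results they bear on had been seen; the turning of array signs was planned.

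In 198 sets of 4 arrays, made of the named genes and the list medians, 1 array lay far from the other 3 in 11, where chance alone would give about 9.9. On replicate 2 these were Actb at 0.20, Ctsl at 0.26, H2-Q4 at 1.06, H2-Q7 at 3.54, Nfkbiz at 1.59, Socs3 at 0.19 and the median of the NF-kappaB list at 0.068. On replicate 1 they were Cxcl9 at 4.22 and Nlrc5 at 4.79, and on replicate 3 Grem1 at −0.013 and the median of the cell cycle exit list at 0.25. Among tested probes with no symbol, which the comparisons did not use, 85 were higher and 133 lower by at least 2-fold.

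Genes that were at least 2-fold lower mostly changed less on a second probe. Another tested probe was not called lower in 38 of 55, against 18 of 73 not called higher among rises. Of 61 genes at least 2-fold lower with an SD over 0.5, the 24 with a second tested probe had a median of −1.55 on the first and −0.14 on the second (quartiles −0.40 and 0.05), while 37 genes had no second probe. The second probe was the dimmer one by the choice of probe, and the genes were chosen for a low first probe, so a smaller change on the second was likely in advance. Whether the whole transcript fell in those 24, or some isoforms only, therefore cannot be decided. The gap between probes was not special to these genes, since the 31 steadier falls with a second probe had medians of −1.14 and −0.16 (quartiles of the second −0.59 and −0.03). Over both sets 4 of 55 second probes were at least 2-fold lower, against 36 of 73 at least 2-fold higher among rises (Fisher's exact test, two-sided, p = 2.32e-07), but the rises were larger to begin with, with medians of 1.87 on the first probe and 0.82 on the second, which favours them in this count. One candidate explanation is cross-hybridisation to a shared source. Across the 61 profiles 1 component held 94.14% of the variance, above each of 1000 random sets of other genes with an SD over 0.5 (median 86.0%, highest 94.09%). Any effect shared by these genes that differs in strength between arrays could give such a share, so it cannot single out such a source. The 61 genes were also chosen for their falls, whereas the random sets were matched on the SD alone. The share falls short of the bound set for a shared source, which was tightened after the value was seen. Of the random sets, 89 passed the share set for it. The 61 genes include the non-coding RNA genes Rn28s1, Rnu2-10 and Rprl2, and the steadier falls include Rpph1 (−1.68) and Rnu1b6 (−1.09). Such genes were therefore not particular to the varying falls, and whether they point to a source was not tested. With 0 arrays of swapped dyes a dye bias of the probes of the 61 genes stays open too.

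Replicate 2 stood apart from the other arrays. It held 716 probes more than 1 log2 unit above the mean of the other arrays and 347 below, against at most 112 and 213 on another array. Of the brightest probes 6.74% departed so far and of the dimmest 0.45%, in sets of equal size, so noise of dim probes does not account for the departures of bright ones. The offset of the background correction shrinks ratios of dim probes, so their low share was likely in advance, and replicate 1 had 2.32% and 0.01%. Replicate 2 also had the lowest Cy5 median (149.5) and the lowest slope (0.91) and correlation (0.985) of the spike-in controls. Poorer signal over the whole array was therefore not excluded. Among the 716 probes 1 component held 68.7% of the variance over 8 channels, within the 63.6% to 80.8% of 100 random sets of bright probes, but among the 116 that departed upward by more than 2 it held 89.1%, with no random sets of that size drawn, and 70.7% of these had no symbol against 29.6% of tested probes, so a shared source stays open. No biological explanation was tested, as the labels give replicate 2 no condition of its own.

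Most calls lay under 2-fold, where a dye bias could add to the ratio. Among 1345 genes called under 2-fold with a second probe, 69.3% of second probes had the sign of the first (95% exact binomial interval 66.8% to 71.8%), 76.0% for rises and 61.4% for falls. Of all second probes 58.9% lay above 0, which is the share to set beside the rises. The falls are to be set beside the smaller remainder, so their lower share does not by itself show poorer agreement. Among 630 genes with p over 0.5, 53.8% of second probes had the sign of the first. The value fell between the bounds set for and against a bias of single probes, so such a bias may contribute and was not excluded, and a bias shared by all probes of a transcript cannot be told apart from the treatment with 0 arrays of swapped dyes. Of the 8 patterns of array signs, 1, the real one, gave 5284 called genes and the highest other gave 0; a share under 0.05 cannot be had from 8 patterns.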

How the results depend on the processing

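Alternatives chosen after seeing the data were leaving out genes whose probes disagree, the probe with the smallest change, and median centring on the tested genes; all others run were planned. Of 168 named genes, 131 were called, and 59 of the 168 had the same call under every setting run. Counts of genes higher and lower stayed within 1.5 times of 3111 and 2173, and those at least 2-fold higher and lower within 1.5 times of 281 and 154, without background subtraction, with an offset of 16, with scaling between arrays, with no filter or a stricter one, with outlier spots kept, with the mean of a gene's probes, with trend and robust fitting, with array weights, with separate channels, and with both added choices of probe. Signal over background limits dim genes, since 1284 were not well above background in the control channel, Cy3, on any array.

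At least 2-fold, Feature Extraction's log ratios gave 779 higher and 368 lower, and the ratios deposited by the authors 778 and 368; of the 281 and 154 genes, 280 and 150 kept the call in each. The methods' t-test called 607 higher and 348 lower after Benjamini-Hochberg, of which 476 and 161 reached 2-fold but held only 244 and 80 of the 281 and 154 genes, and 759 and 362 at the unadjusted threshold with 2-fold. Testing each probe gave 4778 higher, 3633 lower, and 323 at least 2-fold lower, with more items tested. A threshold of 1.5-fold gave 938 and 632, and an adjusted p of 0.01 gave 1570 and 857. With 1 replicate left out, the counts ran from 1600 to 4062 higher, 927 to 2971 lower, 272 to 286 at least 2-fold higher and 124 to 175 at least 2-fold lower, with fewer arrays in each fit. Of 30 lists, 14 passed camera, 11 upward and 3 downward, against 0 with an estimated correlation (lowest adjusted p 0.242, with 3 residual degrees of freedom) and 24 with fry, which does not compare a list with other genes. Fry put the NF-kappaB list, of median −0.043, upward (adjusted p = 0.00238).

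Median centring gave 10495 higher, 4422 at least 2-fold higher and 25 at least 2-fold lower, and it put the median of tested genes at 0.69. Centring on the tested genes gave 4707 higher, 5480 lower, 479 at least 2-fold higher and 2421 at least 2-fold lower. Of the 281 and 154 genes, 280 and 18 kept the call under median centring, and 260 and 95 with centring on the tested genes. The respiratory chain list reversed to 0.89 and 0.22 under these 2 settings, and it passed upward under median centring (camera adjusted p = 0.0353). Under median centring these genes had the sign opposite to that under loess, with log2 ratios of Acta1 0.68, Actg2 0.067, Adamts1 0.040, Asns 0.015, Atg7 0.53, Capn3 0.45, Cav3 0.29, Cd3e 0.33, Cdh2 0.34, Cdk4 0.97, Cdkn1a 0.019, Cox7a1 0.24, Csf1r 0.50, Fcgr3 −0.19, Grem1 0.14, H2-Q4 0.96, Hes1 0.31, Hspb1 1.04, Igf1 0.40, Igfbp2 0.43, Igfbp5 0.95, Irs2 0.48, Itga6 0.026, Itga7 0.96, Itgam 0.90, Map1lc3a 0.40, Mmp15 0.036, Myh3 0.43, Mymk 0.10, Myod1 0.97, Myog 1.02, Ndufv1 0.52, Pfkm 0.31, Ppargc1b 0.0056, Rfxank 0.79, Rplp0 1.05, Socs3 0.88, Tagln 0.40, Traf2 0.89. Those called lower under loess all stayed below 0.69, the median of tested genes, and so stayed low relative to the bulk. Those above 0.69 had not passed under loess. Centring on the tested genes turned the sign of Cdk4 0.30, Dmp1 −0.50, Fcgr3 −0.86, Hspb1 0.37, Itga7 0.29, Myod1 0.29, Rplp0 0.38, Runx2 −0.65. Of these only Dmp1 and Fcgr3 had passed under loess. Dmp1 and Fcgr3 were not well above background in the control channel on any array, so their values here are fitted ones and no measured reversal. The probe with the smallest change reversed Cdh11 −0.021, Csf1r 0.030, Inpp5e 0.062, Tox4 0.58. The cause was not tested for the other differences.

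The call of the respiratory chain list ended without replicate 2 (adjusted p = 0.107), with an offset of 16 (0.0586), with Feature Extraction's ratios (0.0558), the authors' ratios (0.0559), both channels above background (0.0752), each probe (0.124), array weights (0.0787), separate channels (0.135), the methods' t-test (0.229), disagreeing probes left out (0.0503) and the probe with the smallest change (0.0605). Lists that did not pass but did under another setting, with adjusted p, were as follows. Upward under median centring and with centring on the tested genes were the cell cycle exit list (0.0353 and 0.0162), endoplasmic reticulum and heat stress (0.0130 and 0.00207, and 0.0196 with each probe) and house-keeping genes (0.0304 and 0.00352), and downward macrophage markers (0.0353 and 0.0184). With centring on the tested genes alone the transforming growth factor beta list passed upward (0.0471) and endothelial markers downward (0.0406). With each probe on its own, the insulin-like growth factor list (0.0499) and the myogenic list (0.0166, and 0.0315 with the mean of a gene's probes) passed downward, and the metalloproteinase list (0.0499, and 0.0471 with no filter) and the nitric oxide list (0.0116) upward. Osteoblast markers passed upward with no filter (0.0460) and the methods' t-test (0.0449), and adipocyte markers with both channels above background (0.0482). No separate paired analysis applied, because treated and control RNA share each array and the log ratio already pairs them. The spot summary and saturation alternatives were not run.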

Other observations

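The genes named in this part were chosen after their values were seen, as were the test on histone genes and its bounds. Outside the lists, rises included further interferon-related genes. Ifi27l2a rose by 3.76, Serpina3f, a serine protease inhibitor, by 3.72, Uba7, the activating enzyme for ISG15, by 3.05, Lgals3bp by 2.91, Cd274, which encodes the checkpoint ligand PD-L1, by 2.41 and Ubd, a ubiquitin-like modifier, by 2.44. F3, which encodes tissue factor, rose by 2.14 and Xdh by 1.96. Among steady falls, each with 1 tested probe only, Chrnd, a subunit of the muscle acetylcholine receptor, had −1.45 and Dhrs7c, a protein of the sarcoplasmic reticulum, had −1.62.

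Some replication-dependent histone genes fell under loess, and the others did not pass, but under median centring the median of these genes turned to 0.13, with 17 higher and 13 lower, against 0.69 for all tested genes. Centring on the tested genes, chosen after seeing the data, gave −0.54, with 4 higher and 23 lower. Under loess, of 40 tested histone genes of these clusters, 0 rose and 21 fell, 5 of them at least 2-fold, and the median of the 40 was −0.46. The set was put together after the values were seen, and no test of it as a whole was run. H2ac4 had −1.97, H4c12 −1.73 and H4c4 −1.68. One hypothesis was that the histone genes share the source behind the varying falls, which were much lower on replicate 2. The median histone gene had −0.32 on replicate 2, against −0.44, −0.39 and −0.35 on replicates 1, 3 and 4, and its departure on replicate 2 was −0.08 (quartiles −0.61 and 0.18), where the varying falls had −1.35. This argues against that source for the median histone gene only. The 5 genes at least 2-fold lower were each lowest on replicate 2, with −2.58 to −2.30, and of these H1f4, H4c4, H4c12 and H4c14 are among the varying falls. For these 5 the source stays open. These probes may also read related histone genes, which the files cannot separate.

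The spike-in controls of the arrays had intercepts of −0.90, 0.10, −1.21 and −0.28 on the log2 scale for replicates 1 to 4, with slopes of 0.91 to 0.97. What the spread of these intercepts means was not tested. Because the loess sets ratios relative to the bulk of probes on each array, a change of all transcripts together would not be seen.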
